A study of Mus musculus with 9 samples.

How the data were processed

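Messenger RNA was sequenced from 9 mouse libraries labelled as spleen, 3 in each of 3 groups. The groups were taken from the sample titles: blank control, disease group (called model here) and disease group with AVFP therapy (called AVFP here). Libraries are named by group and by the number in their title. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and the cDNA was ligated to adaptors, amplified and circularised.

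The authors' deposited table gives 3 values per gene and library: an estimated count, TPM and FPKM. The estimated counts, per the file headers read counts, were not whole in 10.5% of values, as deposited. TPM and FPKM were computed by the authors and deposited to 2 decimals. A human assembly, GRCh38.p13, is the genome build named in the submitters' processing notes, while gene identifiers and symbols in the table are those of mouse, so no coordinates are given. The aligner, the counting tool, its version, the annotation and the strand setting are not given in the sources used here. Reads of near-identical genes (Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt, Saa1 with Saa2, Hamp with Hamp2, and the major urinary protein genes) could have been split between copies by that counting, and values of single members are uncertain for this reason. The table's 9 further value columns were not used, and its own gene symbols were used as names.

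The table held 16623 genes. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10), which left 12292 genes. Libraries were scaled with TMM, and all 9 libraries entered 1 robust quasi-likelihood fit (glmQLFit, glmQLFTest) with 1 coefficient per group and no covariate. The 3 comparisons were model against control, AVFP against model and AVFP against control. Benjamini-Hochberg adjusted p under 0.05 was the threshold, with no minimum fold. CPM values were computed from TMM-scaled library sizes, and means are given with SD over 3 libraries. Log2 fold changes are edgeR's, with their standard errors (SE). The common biological coefficient of variation was 0.266.

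Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01. A total of 35 lists was fixed before the data were examined, for cell types and pathways of a spleen after cyclophosphamide and for neighbouring tissues. Lists with at least 3 tested genes entered, which left 30 lists in 3 comparisons, and p-values were adjusted over these 90 tests. A further 16 lists for liver functions were chosen after the data were examined and after single genes of some of them had been seen. They were adjusted as a family of 48 tests of their own and are not independent evidence of direction. Camera was repeated with an estimated correlation, and the rotation test fry was run as a test of each list on its own. Medians of lists in the text are of edgeR log2 fold changes, except where limma voom is named. Member genes were also counted with p-values adjusted over the list alone.

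Genes named singly followed a rule fixed before the data were examined: the 10 largest rises and the 10 largest falls past the threshold, or, where none passed, the 5 genes with the smallest p in each direction. In both cases the values of the compared groups had to be without overlap, the higher group had to have a mean of at least 5 CPM, and symbols of the form Gm with digits or ending in Rik were passed over. Applying these conditions also where none passed was decided after the data were seen. From lists, members that passed when adjusted over the list alone were named by size of change, and where none passed the 2 with the highest mean expression. Other genes were chosen after their values were seen, and are marked so. Some results are not reported here.

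A floor of 3 counts over a group was used for fold changes against a group at 0. Floors cover counting error only. Depth was 13317202 to 16929183 estimated counts per library. The fit was tested on simulated data: in 3 simulated sets for model against control, each with the 12292 real gene means and library sizes, 84 of 300 genes changed 2-fold (28.0%) and 242 of 300 genes changed 4-fold (80.7%) were called, and 17 of all 343 calls were false. Simulated counts were drawn independently for each gene and held no libraries that stand apart, so recovery in the real libraries can be lower.

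Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a stricter filter of 1 CPM in all 3 libraries of a group, only the 6 libraries compared, the replicate number as a block, voom with sample quality weights, an adjusted p under 0.1, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data left out 6 genes with discordant values, left out the libraries control 1 and AVFP 3 together, or used limma voom with equal weights. An alternative pseudocount did not apply, since the tests ran on counts. For pairs of comparisons that share libraries, 100 simulated sets of unchanged groups gave the covariance that sharing alone produces. TPM and FPKM were compared gene by gene within each library, for genes with both at least 1 and with a tolerance of 2% around the library's median ratio. Principal components used the 500 most variable genes. Pairs of libraries were compared by chi-square of their counts, and 0 pairs were identical. Genes for immunoglobulin constant regions, T cell receptor constant regions and the mitochondrial genome, and Xist, were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.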

Results

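Messenger RNA was sequenced from 9 mouse libraries labelled spleen, with 3 libraries in each of 3 groups. The control group was a blank control, the model group was the disease group, and the AVFP group was the disease group given AVFP. By the series title the disease is immune suppression by cyclophosphamide, an alkylating drug that acts on dividing cells, and the treatment is a polysaccharide preparation from flowers of the plant Apocynum venetum. All 9 libraries, controls included, carry the treatment label immunosuppression. Estimated counts summed to 14564229, 15600799 and 16652461 in control libraries 1 to 3, to 16929183, 16516415 and 16602255 in model libraries 1 to 3, and to 13317202, 14274679 and 16455742 in AVFP libraries 1 to 3. Between 14353 and 14905 genes had a count in each library, and 12292 genes were tested. The labels do not say that the 3 samples of a group are separate animals, so p-values measure only the spread between these samples. The lowest chi-square per degree of freedom between any pair of libraries was 26.4, which argues against repeat sequencing of the same library. Other technical spread, and whether the samples are separate animals, stay open.

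Transcripts of proteins that hepatocytes secrete led all 9 libraries. Apoa2, an apolipoprotein of high density lipoprotein, lay between 43819 and 68188 TPM, and Alb, serum albumin, between 14727 and 69449 TPM. The 20 genes of the hepatocyte list held 23.7% to 34.1% of the 1000000 TPM of a library. B cell and T cell genes were close to 0: Cd79a, part of the B cell receptor, reached at most 1.98 TPM, and Ptprc, the pan-leukocyte antigen CD45, at most 2.83 TPM. Genes of the B cell and T cell lists together came to 0.0038% to 0.0125% of the hepatocyte list. Clec4f, a lectin of Kupffer cells (the macrophages of the liver), exceeded Spic, a transcription factor of splenic red pulp macrophages, in 9 of 9 libraries, by 5.41 to 20.8 times. Of the list members in the table, only 6 of 20 B cell, 7 of 19 T cell and 3 of 16 NK and cytotoxic genes had enough counts to be tested. The T cell list had 22 members, and those not in the table could not be tested.

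**Figure D1:**
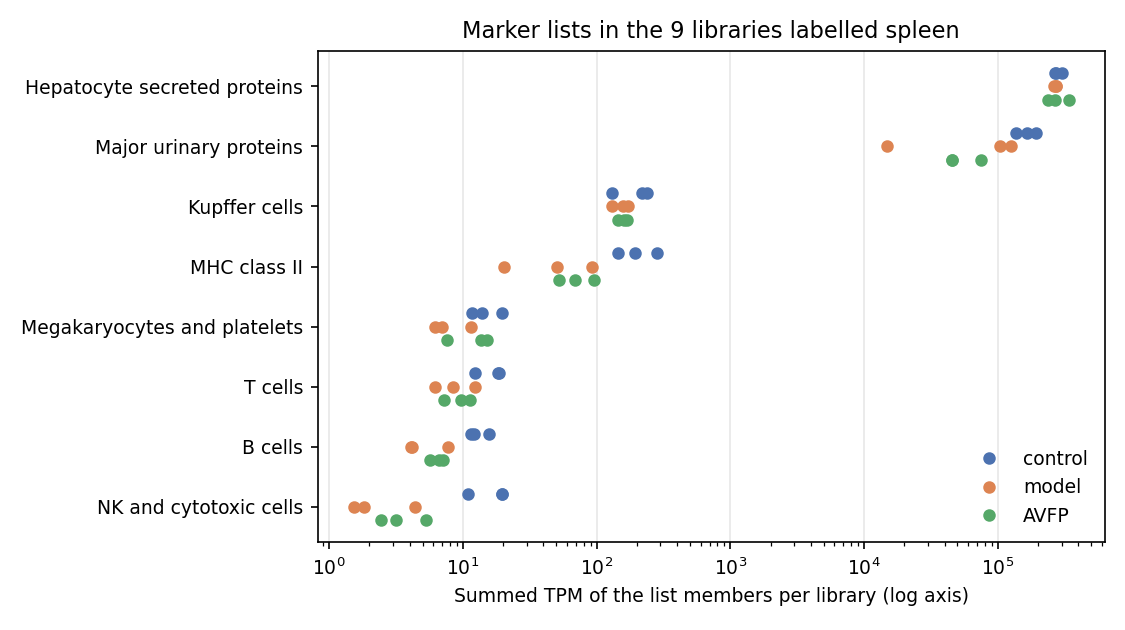
Summed TPM of marker lists (log axis) in each library, with 1 point per library and colours for control, model and AVFP. The hepatocyte list lay between 23.7% and 34.1% of 1000000 TPM, while the B cell list lay between 4.11 and 15.5 TPM in all 9 libraries.

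Single libraries stood apart within their groups. On principal components of the 500 most variable genes (PC1 32.9%, PC2 19.6% of variance), AVFP 3 lay at 34.2 and 23.5, while the other AVFP libraries lay at 10.1 and -12.9 and at -3.15 and -20.3. Its limma quality weight was 0.185, against 0.795 to 3.70 in the other 8 libraries. Eif2s3y, a gene of the Y chromosome, was at 1.09 TPM in AVFP 3 and at 11.8 to 25.1 TPM in the others, and the labels used here give no sex. In control 1, S100a8, a calcium-binding protein of neutrophils, was at 586 TPM, against 40.5 and 11.6 TPM in controls 2 and 3. The major urinary protein Mup1 was at 859 TPM in model 3, against 43417 and 24926 TPM in models 1 and 2.

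The comparison of model with control asks what cyclophosphamide immune suppression changes. Hepcidin (Hamp, gene ID 84506), the hormone that restrains iron release into plasma, averaged 6704.5 ± 1081.8 CPM in the model and 695 ± 581 CPM in control (SD, n = 3 per group), a log2 fold change of 3.27 ± 0.56 (SE). Id1 (gene ID 15901), a helix-loop-helix inhibitor induced by BMP signalling, averaged 20.1 ± 10.1 CPM against 2.04 ± 1.13 CPM, a log2 fold change of 3.30 ± 0.42 (SE). Haemoglobin alpha (Hba-a2, gene ID 110257) averaged 0.0659 ± 0.114 CPM in the model and 5.50 ± 2.08 CPM in control, a log2 fold change of -6.29 ± 0.80 (SE). G6pc (gene ID 14377), the catalytic subunit of glucose-6-phosphatase, which releases glucose from the liver, averaged 111 ± 41.8 CPM against 333 ± 75.3 CPM, a log2 fold change of -1.59 ± 0.29 (SE). None of these passed over all genes in the main edgeR fit.

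With edgeR's quasi-likelihood test, 0 genes passed Benjamini-Hochberg adjusted p under 0.05 in model against control. The smallest adjusted p was 0.157, and 1001 genes had an unadjusted p under 0.05. DESeq2 called 71 genes (33 higher and 38 lower in the model), limma voom with sample quality weights called 126 (52 and 74), and 42 genes were called by both. With only the 6 libraries compared, edgeR called 13 genes. Without control 1 it called 2 (Hamp and Id1), and without model 1 it called 3 (Hbb-bs, Angptl8 and Id1), genes named after their values were seen. Apart from Hamp and Id1, the genes with the smallest p and higher values in the model were Mgst3 (log2 fold change 1.02), a microsomal glutathione transferase, Angptl8 (1.91), a secreted regulator of lipoprotein lipase, and Hp (1.30), haptoglobin, which binds free haemoglobin. Those with lower values, besides Hba-a2 and G6pc, were Samhd1 (-1.01), a nucleotide hydrolase, Lsp1 (-2.62), a leukocyte protein, and Ugt3a2 (-1.28), a glycosyltransferase. The adjusted p of these 10 genes lay between 0.157 and 0.285 with edgeR.

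Lymphocyte and antigen presentation lists fell in the model. All 9 tested MHC class II genes were below 0, with a median log2 fold change of -1.08 (limma camera adjusted p = 1.7e-05, adjusted p = 0.69 with an estimated correlation). Of these, in the main edgeR fit, 0 passed over all genes and 3 fell when adjusted over the list alone: H2-Aa (-2.06), H2-Ab1 (-1.78) and H2-Eb1 (-1.69). All 6 tested B cell genes were below 0, with a median of -0.85 (camera adjusted p = 0.0016, adjusted p = 0.69 with an estimated correlation), and Cd79a fell when adjusted over the list alone (-2.01; 0.247 ± 0.0474 CPM in the model, 1.02 ± 0.208 CPM in control, n = 3 per group). The T cell list fell too, with 6 of 7 genes below 0 and a median of -0.94 (camera adjusted p = 0.011, adjusted p = 0.69 with an estimated correlation), and 0 members passed over the list alone. Zap70 (-0.21) and Tcf7 (-0.17), its members with the highest mean CPM, did not pass. The 3 tested NK and cytotoxic genes Nkg7 (-2.49), Ccl5 (-2.32) and Klrk1 (-1.89) all fell when adjusted over the list alone (camera adjusted p = 3.4e-04, adjusted p = 0.36 with an estimated correlation). In the monocyte and macrophage list 12 of 13 genes were below 0, and Ccr2, a chemokine receptor of inflammatory monocytes, fell over the list alone (-2.34). That list's camera adjusted p was 0.011, with adjusted p = 0.82 with an estimated correlation, and it was 0.182 without model 2. None of the members of these lists passed over all genes in the main edgeR fit.

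In the erythroid list 7 of 9 genes were below 0 (camera adjusted p = 1.7e-05, adjusted p = 0.36 with an estimated correlation), and the 4 haemoglobin genes Hbb-bs (-6.64), Hba-a2 (-6.29), Hba-a1 (-5.88) and Hbb-bt (-5.29) fell over the list alone. Because the other members moved little, the median was -0.47 and the mean -2.73. Hba-a1 lay at 1120, 611 and 1705 TPM in controls 1 to 3 and at 41.8, 1.04 and 0.82 TPM in models 1 to 3. The neutrophil list did not pass camera (adjusted p = 0.137), with a median of -6.19. Over the list alone 6 of its 8 genes fell, among them Ngp (-10.15), Ltf (-9.25) and S100a8 (-7.82), and 2 rose, Lcn2 (2.30) and Wfdc21 (0.93), which hepatocytes also make in the acute phase. In the neutrophil precursor list Mpo (-6.13), Elane (-4.43) and Hk3 (-0.88) fell over the list alone, and camera adjusted p was 0.093. The size of these changes rests on control 1, where Elane was at 63.5 TPM and Mpo at 21.2 TPM, against 3.31 and 2.48 TPM and 0.89 and 0.77 TPM in controls 2 and 3. Jchain, the joining chain of secreted immunoglobulin, fell when adjusted over the plasma cell list alone (-3.55), whose camera adjusted p was 0.694.

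Ribosomal protein genes rose as a list. All 22 tested genes were above 0, with a median log2 fold change of 0.39 (camera adjusted p = 6.5e-07, adjusted p = 0.82 with an estimated correlation). In the main edgeR fit 0 passed over all genes or over the list alone. Rps2 (0.48) and Rpl4 (0.15) had the highest mean CPM. Of the 30 lists tested in model against control, 1 rose and 6 fell by camera with the preset correlation. With an estimated correlation 0 passed, and by fry 2 passed.

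Among the lists chosen after the data were examined, the BMP and hepcidin list rose, with 12 of 15 genes above 0 (camera adjusted p = 6.3e-07, adjusted p = 0.14 with an estimated correlation). Over the list alone 7 rose: Id1, Hamp, Hamp2 (1.59), Id3 (1.54), Atoh8 (0.96), Smad7 (0.91) and Id2 (0.60). Cholesterol synthesis fell, with 20 of 20 genes below 0, a median of -0.78 and 12 members lower over the list alone (camera adjusted p = 3.3e-11, adjusted p = 0.53 with an estimated correlation). Idi1, isopentenyl diphosphate isomerase, averaged 14.2 ± 7.60 CPM in the model and 76.2 ± 46.0 CPM in control (SD, n = 3 per group; log2 -2.43), and Sqle, squalene epoxidase, changed by -1.75. The acute phase list rose, with 16 of 16 genes above 0 and a median of 1.57, and 0 members passed over the list alone (camera adjusted p = 3.2e-08, adjusted p = 0.65 with an estimated correlation). Its members Saa1 and Saa2, serum amyloid A proteins, averaged 9103.5 ± 6414.7 and 9176.7 ± 4827.7 CPM in the model, against 2194.4 ± 602 and 1932.5 ± 655 CPM in control. The urea cycle list rose, with 8 of 9 genes above 0 and a median of 0.37 (camera adjusted p = 0.0023, adjusted p = 0.44 with an estimated correlation), and 0 passed over the list alone, Ass1 (0.38) and Cps1 (0.23) being highest in mean CPM. The list summed to 3397.6, 3839.3 and 3468 TPM in models 1 to 3 and to 3012, 3158.1 and 3915.3 TPM in controls 1 to 3. Control 3 thus lay above each model library, and controls 1 and 2 lay below.

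The other added lists that passed in model against control each lost the call without 1 library. The major urinary protein list fell (camera adjusted p = 0.0018, adjusted p = 0.67 with an estimated correlation), and without model 3 its adjusted p was 0.538. Its summed TPM was 103310, 124780 and 14784 in models 1 to 3 and 135870 to 194330 in control. The metallothionein list rose (camera adjusted p = 0.046, adjusted p = 0.67 with an estimated correlation), with Mt1 (2.17) and Mt2 (2.01) higher over the list alone. Its adjusted p lay between 0.0508 and 0.15 without control 2, control 3, model 1, model 3, AVFP 1 or AVFP 3. The hepatocyte list rose with a median of 0.20 (camera adjusted p = 0.019, adjusted p = 0.67 with an estimated correlation), with 0.121 without control 1, 0.0846 without model 1 and 0.0703 without model 2. Its summed TPM did not follow the median: 263000, 271810 and 275210 in models 1 to 3 and 272270, 267660 and 300300 in controls 1 to 3. The stellate cell list fell (camera adjusted p = 0.010, adjusted p = 0.67 with an estimated correlation), with 0.371 without control 3 and 0.196 without model 2.

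**Figure D2:**
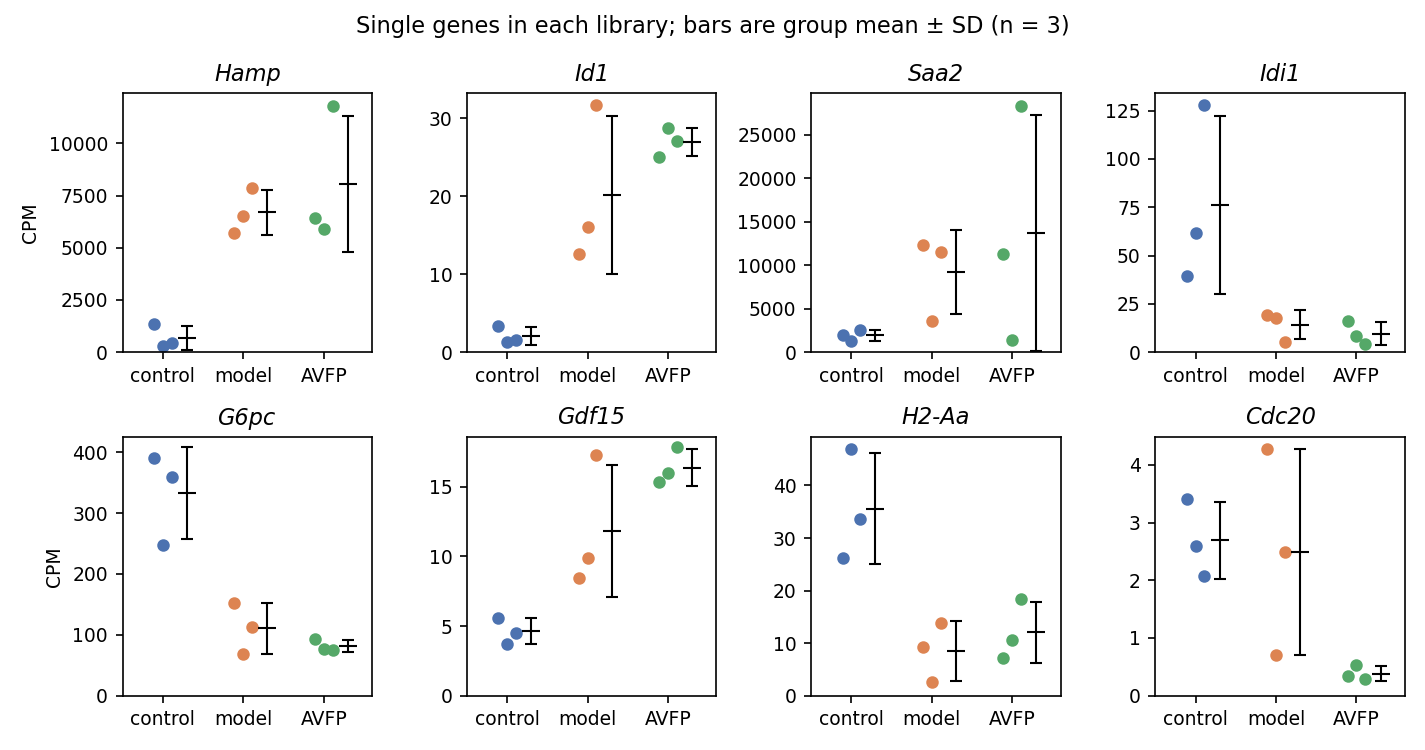
CPM of 8 genes in each library of the control, model and AVFP groups, with group mean ± SD (n = 3). Hamp averaged 695 CPM in control and 6704.5 CPM in the model, and Gdf15 averaged 4.62, 11.9 and 16.4 CPM in control, model and AVFP; Saa2, Idi1, H2-Aa and Cdc20 were chosen after their values were seen.

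The comparison of AVFP with model asks what the polysaccharides change on top of the disease. Sfi1 (gene ID 78887), a centrin-binding protein of the centrosome, averaged 209 ± 32.7 CPM with AVFP and 63.7 ± 12.9 CPM in the model (SD, n = 3 per group), a log2 fold change of 1.72 ± 0.34 (SE). Cldn2 (gene ID 12738), a tight junction protein, averaged 42.6 ± 1.27 CPM against 68.8 ± 4.96 CPM, a log2 fold change of -0.69 ± 0.15 (SE). Haptoglobin (Hp, gene ID 15439) averaged 4918.1 ± 897 CPM against 15304 ± 1806.4 CPM, but TPM and FPKM of Hp disagree in AVFP 1 and AVFP 3, so its level there is uncertain. None of these passed over all genes in the main edgeR fit.

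With edgeR, 0 genes passed in AVFP against model. The smallest adjusted p was 0.598, reached by Hp, and 668 of the 12292 tested genes had an unadjusted p under 0.05. Without the 6 genes with discordant values, Hp among them, the smallest adjusted p was 0.865. DESeq2 called 6 genes, 2 higher and 4 lower with AVFP, among them Sfi1, Hp and Cldn2. Limma voom with quality weights called 0. Without AVFP 2, edgeR called 1 gene, Slc15a2, a peptide transporter named after its value was seen. Other genes with the smallest p were Fnbp1 (0.66), Chd7 (0.90), Hes1 (0.87), a target of Notch signalling, and LOC115489417 (0.75), with higher values, and Gpd2 (-0.74), a mitochondrial glycerol-3-phosphate dehydrogenase, and Spcs1 (-0.83), a signal peptidase subunit, with lower values. Their edgeR adjusted p was 0.864.

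The cell cycle list fell with AVFP, with 18 of 22 genes below 0 and a median log2 fold change of -0.73 (camera adjusted p = 7.1e-05, adjusted p = 0.82 with an estimated correlation). Of its members, in the main edgeR fit, 0 passed over all genes and 1 fell when adjusted over the list alone, Cdc20, an activator of the anaphase-promoting complex (0.381 ± 0.127 CPM with AVFP, 2.50 ± 1.79 CPM in the model, n = 3 per group; log2 -2.68). Libraries differed within groups: the summed TPM of the list was 50.8, 126 and 44.9 in AVFP 1 to 3 and 88.0, 100 and 61.5 in models 1 to 3, so AVFP 2 was the highest. Thymidine kinase (Tk1) made 96.7 TPM of the sum in AVFP 2, while Cdc20 was at 0.40 TPM there and at 0.44 TPM or more in each model library. The interferon response list fell, with 13 of 18 genes below 0 and 0 passing over the list alone (camera adjusted p = 0.0020, adjusted p = 0.84 with an estimated correlation). Stat2 (0.44) and Bst2 (-0.48), its members with the highest mean CPM, did not pass. Its adjusted p was 0.195 without model 3, 0.191 without AVFP 1 and 0.0839 without AVFP 3. The stroma and extracellular matrix list rose, with 10 of 12 genes above 0 and a median of 0.52 (camera adjusted p = 0.0016, adjusted p = 0.82 with an estimated correlation), and its adjusted p was 0.190 without model 2. Its summed TPM was 313, 245 and 202 in AVFP 1 to 3, against 219 to 251 in the model, so only AVFP 1 lay above each model library. Members Col1a1 (1.46) and Col6a1 (0.88), named after their values were seen, did not pass over the list alone. The antioxidant list fell, with 13 of 19 genes below 0 and a median of -0.09 (camera adjusted p = 0.032, adjusted p = 0.82 with an estimated correlation), and its adjusted p was 0.131 without model 1, 0.0750 without model 3 and 0.582 without AVFP 1. Its summed TPM in AVFP 2 was 9790, above each model library (8511 to 9038.1). Its members with the highest mean CPM, Cat (-0.18), catalase, and Gstm1 (-0.31), a glutathione transferase, did not pass.

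Immune lists that had fallen in the model did not pass in AVFP against model. The median of the B cell list was 0.30 (camera adjusted p = 0.903), that of the T cell list 0.18 (0.505), that of the NK and cytotoxic list 0.27 (0.475), that of the MHC class II list 0.47 (0.102) and that of the monocyte and macrophage list 0.20 (0.962, with a test direction below 0). The neutrophil list had a median of 0.28 and a mean of -0.29 (0.521). H2-Aa averaged 12.0 ± 5.79 CPM with AVFP, 8.53 ± 5.70 CPM in the model and 35.6 ± 10.5 CPM in control (SD, n = 3 per group). Of the lists chosen after the data were examined, 4 fell with AVFP: cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and cytochrome P450. Cholesterol synthesis had 16 of 20 genes below 0 (camera adjusted p = 5.0e-05, adjusted p = 0.67 with an estimated correlation). Fatty acid synthesis had 12 of 14 below 0 (camera adjusted p = 2.6e-04, adjusted p = 0.53 with an estimated correlation), and its adjusted p was 0.0807 without AVFP 3. Its summed TPM was 755, 860 and 355 in AVFP 1 to 3 and 530, 569 and 971 in models 1 to 3. In that sum AVFP 1 and AVFP 2 lay above models 1 and 2. Fatty acid oxidation had 14 of 18 below 0 (camera adjusted p = 0.0023, adjusted p = 0.67 with an estimated correlation), with 0.189 without AVFP 1 and 0.0807 without AVFP 3, and summed to 14428 TPM in AVFP 2, above each model library (8977.3 to 10411). Cytochrome P450 had 14 of 16 below 0 (camera adjusted p = 0.0035, adjusted p = 0.67 with an estimated correlation), with 0.0844 without model 2 and 0.820 without AVFP 3, where its limma voom median turned to 0.10. It summed to 14653 TPM in AVFP 2, also above each model library.

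The comparison of AVFP with control asks how far treated animals differ from blank controls. Id1 averaged 26.9 ± 1.84 CPM with AVFP and 2.04 ± 1.13 CPM in control (SD, n = 3 per group), a log2 fold change of 3.72 ± 0.43 (SE). Gna14 (gene ID 14675), a G protein alpha subunit, averaged 0.873 ± 0.307 CPM against 7.82 ± 1.86 CPM. Gdf15 (gene ID 23886), a stress-induced cytokine and p53 target, averaged 16.4 ± 1.33 CPM against 4.62 ± 0.939 CPM. Hba-a2 had 0 counts in all 3 AVFP libraries, which puts it at least 81.3-fold lower than in control against a floor of 0.0677 CPM over the group. None of these passed over all genes in the main edgeR fit, while DESeq2 called Id1, Gna14, Gdf15 and Hba-a2.

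With edgeR, 0 genes passed in AVFP against control. The smallest adjusted p was 0.0508, reached by Id1, and 1966 genes had an unadjusted p under 0.05. DESeq2 called 301 genes (148 higher and 153 lower with AVFP), limma voom with quality weights called 8, and 7 were called by both. With no filter edgeR called 15 genes, with only the 6 libraries compared 9, and at an adjusted p under 0.1 it called 19. Leaving out a library gave 70 genes without AVFP 2, 10 without model 1, 9 without model 3, 4 without model 2 (among them Id1, G6pc and Gna14), 2 without control 1 (Id1 and Hamp) and 2 without AVFP 3 (Paqr9 and Ablim3). Other genes with the smallest p were Banp (1.69), Angptl8 (2.26) and Hes1 (1.38), with higher values, and G6pc (-2.03) and Snx7 (-1.19), a sorting nexin, with lower values. The edgeR adjusted p of these 5 genes and of Id1, Gna14, Gdf15 and Hba-a2 lay between 0.0508 and 0.0563.

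Proliferation and interferon lists were lower with AVFP than in control. In the cell cycle list 20 of 22 genes were below 0, with a median of -1.19 (camera adjusted p = 1.7e-05, adjusted p = 0.82 with an estimated correlation). The summed TPM of AVFP 2 (126) was above each control library, with Tk1 at 96.7 TPM. Over the list alone 6 fell, among them Cdc20 (-2.79), Ccnb1 (-2.20) and Ccnb2 (-2.08), the latter a pair of mitotic cyclins. In the interferon list 17 of 18 genes were below 0 (camera adjusted p = 5.6e-04, adjusted p = 0.82 with an estimated correlation), and Ifit2 (-1.94), Rsad2 (-1.36), Ifi44 (-0.98) and Ifit3 (-0.96) fell over the list alone. The p53 target list rose, with 14 of 18 genes above 0 (camera adjusted p = 0.018, adjusted p = 0.82 with an estimated correlation), Gdf15 (1.82) and Phlda3 (2.04) rose over the list alone, and its adjusted p was 0.129 without AVFP 1. None of the members of these lists passed over all genes in the main edgeR fit. DESeq2 called members of each list, among them Cdc20, Ifit2 and Gdf15.

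Immune lists were below control with AVFP as well. The B cell list fell, with 6 of 6 genes below 0, and Cd79a (-2.63) fell over the list alone (camera adjusted p = 0.018, adjusted p = 0.82 with an estimated correlation, and 0.135 without AVFP 1). The NK and cytotoxic list fell, with 3 of 3 genes lower over the list alone (camera adjusted p = 0.011, adjusted p = 0.58 with an estimated correlation). The MHC class II list fell, with 8 of 9 genes below 0 and 0 passing over the list alone (camera adjusted p = 0.013, adjusted p = 0.82 with an estimated correlation). Cd74 (-1.05) and H2-Aa (-1.56) had the highest mean CPM. The adjusted p of the list was 0.0502 without control 2, 0.102 without AVFP 1 and 0.117 without AVFP 2. The monocyte and macrophage list fell (camera adjusted p = 0.037, adjusted p = 0.84 with an estimated correlation), with 0.288 without AVFP 1 and 0.361 without AVFP 2, and Ccr2 (-2.72) fell over the list alone. In AVFP 3 it summed to 423 TPM, above each control library (238 to 337). The neutrophil list fell (camera adjusted p = 0.049, adjusted p = 0.85 with an estimated correlation), with 0.0702 without AVFP 2. Over the list alone 6 of its 8 genes fell, among them Ngp (-10.05) and S100a8 (-7.06), and Wfdc21 (0.70) rose. The erythroid list fell (camera adjusted p = 3.3e-04, adjusted p = 0.55 with an estimated correlation), with a median of -0.81, also with genes at 0 set to their bounds. Over the list alone the 4 haemoglobin genes and Car2 (-0.81) fell and Klf1 (0.97), an erythroid transcription factor, rose; Hbb-bt, at 0 counts in AVFP, was at least 372-fold lower than in control. The T cell list did not pass (0.180). The ribosomal protein list rose, with 20 of 22 genes above 0 (camera adjusted p = 0.0018, adjusted p = 0.86 with an estimated correlation), and its adjusted p was 0.658 without AVFP 3.

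Among the lists chosen after the data were examined, cholesterol synthesis fell with AVFP against control, with 20 of 20 genes below 0, a median of -1.18 and 16 members lower over the list alone (camera adjusted p = 2.7e-15, adjusted p = 0.46 with an estimated correlation). Idi1 changed by -3.01, and Hmgcs1, the hydroxymethylglutaryl-CoA synthase of that pathway, by -1.87. The BMP and hepcidin list rose, with 11 of 15 genes above 0 and 6 higher over the list alone, among them Id1 (3.72), Hamp (3.53) and Id3 (1.67) (camera adjusted p = 4.6e-04, adjusted p = 0.30 with an estimated correlation). Fatty acid oxidation fell, with 17 of 18 genes below 0 and 0 passing over the list alone (camera adjusted p = 2.6e-04, adjusted p = 0.65 with an estimated correlation). AVFP 2 stood apart at 14428 TPM, within the controls (10903 to 14731), against 5804.2 and 5706.1 TPM in AVFP 1 and AVFP 3. The acute phase list rose, with 16 of 16 genes above 0 (camera adjusted p = 1.4e-04, adjusted p = 0.67 with an estimated correlation), and its adjusted p was 0.110 without AVFP 3, with a limma voom median of 0.36. Its summed TPM was 80444, 21307 and 135740 in AVFP 1 to 3 and 25133, 21761 and 31982 in controls 1 to 3, so AVFP 2 lay below each control. The metallothionein list rose (camera adjusted p = 0.032, adjusted p = 0.67 with an estimated correlation), with 0.0672 without AVFP 1 and 0.195 without AVFP 3. The major urinary protein list fell (camera adjusted p = 0.0060, adjusted p = 0.71 with an estimated correlation), with 0.0807 without AVFP 3.

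**Figure D3:**
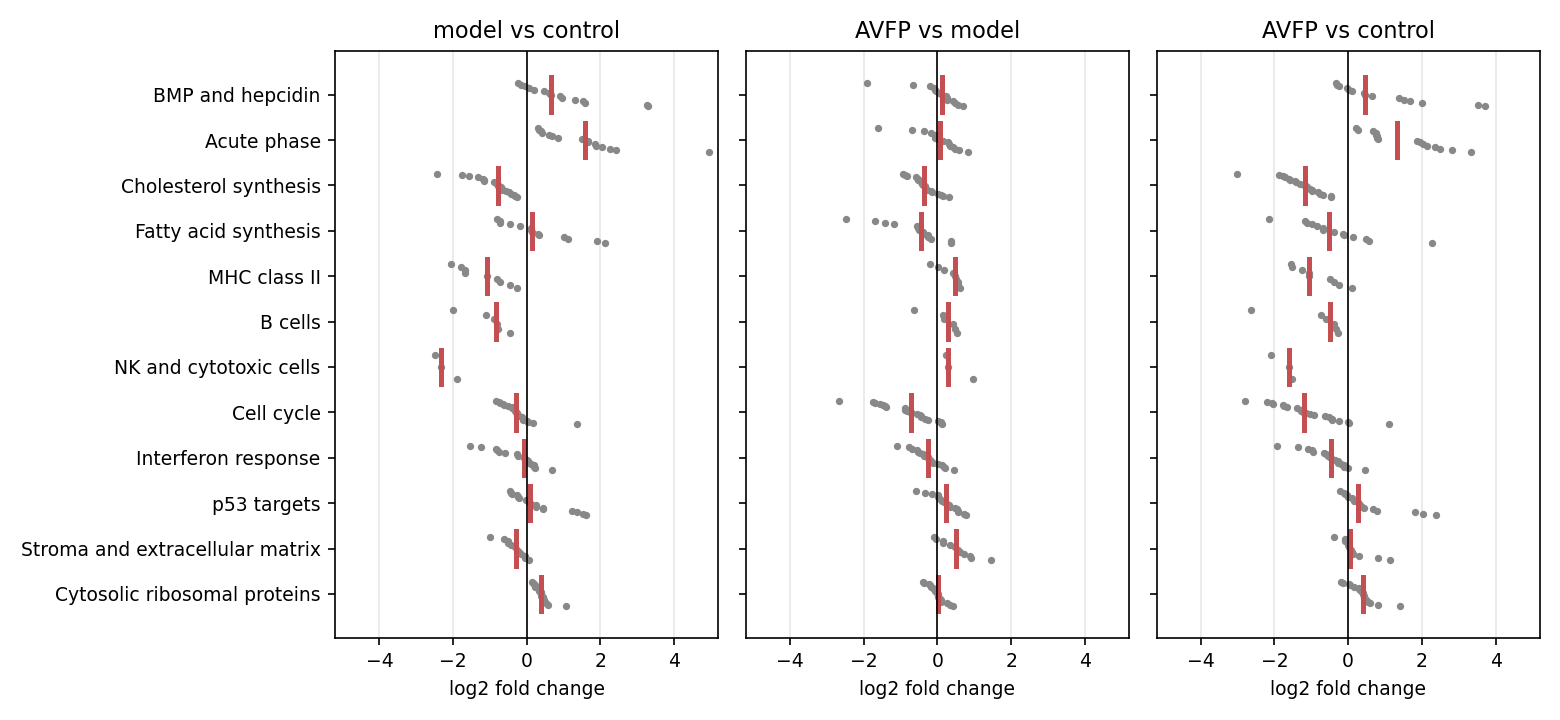
Log2 fold changes (horizontal axes) of the tested members of 12 gene lists in the 3 comparisons, with 1 grey point per gene and a red bar at the list median. The cholesterol synthesis median was -0.78 in model against control, -0.38 in AVFP against model and -1.18 in AVFP against control; the MHC class II median was -1.08, 0.47 and -1.05.

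Whether AVFP moved genes against the model change was asked over all 12292 genes. With edgeR 0 genes were called in both model against control and AVFP against model, and DESeq2 called 2 in opposite directions, Hp and Gm7429. Hp is among the genes whose values disagree in AVFP 1 and AVFP 3. Of the 1001 genes with unadjusted p under 0.05 in model against control, 656 (65.5%) had the opposite sign in AVFP against model, and 955 (95.4%) had the same sign in AVFP against control. The 2 comparisons share the model libraries, which alone gives opposite signs: across genes, which are not independent replicates, the covariance of log2 fold changes was -0.0352, and unchanged groups simulated with the same sharing gave -0.0703. With separate model libraries for the 2 comparisons the covariance was 0.0216 (range 0.0039 to 0.0319). For model against control and AVFP against control, which share the control libraries, the covariance was 0.196, against 0.0704 in simulated unchanged groups and 0.149 (0.133 to 0.163) with separate control libraries.

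Cytokine genes of the list fixed before the data were examined were low. Il18, an interleukin of the IL-1 family, averaged 15.5 ± 0.982 TPM in control, 18.7 ± 1.69 TPM in the model and 16.3 ± 3.92 TPM with AVFP (SD, n = 3 per group). Il1b averaged 2.31 ± 1.03, 0.493 ± 0.187 and 0.633 ± 0.681 TPM in the same order, Tgfb1 averaged 4.14 ± 0.715, 3.24 ± 0.945 and 3.27 ± 1.38 TPM, and Csf1 averaged 3.52 ± 0.764, 3.06 ± 1.02 and 3.48 ± 0.569 TPM. Tnf averaged 0.46 ± 0.354, 0.0567 ± 0.0666 and 0.16 ± 0.0557 TPM, and Il6 reached at most 0.14 TPM in any library. Il1a averaged 1.64 ± 0.472, 1.31 ± 0.252 and 1.18 ± 0.401 TPM, and Il15 averaged 0.853 ± 0.170, 0.787 ± 0.311 and 0.710 ± 0.298 TPM. Il10, Il12b, Ifng, Csf2 and Csf3 were at most 0.15 TPM in any library. Of the 20 genes of the list, 13 were in the table and 6 had enough counts to be tested. The list did not pass in any comparison (camera adjusted p = 0.959, 0.475 and 0.632 in model against control, AVFP against model and AVFP against control). Its median was -0.04 in model against control with a test direction above 0, and -0.04 in AVFP against model with a mean of 0.02.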

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

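The explanations weighed here and what they predict were written only after the result was seen; fits of the 6 libraries compared and fits without 1 library were fixed before. Haptoglobin (Hp) and lipocalin 2 (Lcn2), 2 acute phase proteins of hepatocytes, head a set of 6 genes whose deposited FPKM stand apart from their TPM in AVFP 1 and again in the same 6 genes in AVFP 3, against 0 such genes in each control library. The other 4 are Bcl3, Lbp, Gstp2 and Cebpd. FPKM values were not used in any comparison, and this signal in unused values is why the result is listed. Hp was at 3106.7 TPM and 4683.2 FPKM in AVFP 1, at 6160 TPM and 3862.3 FPKM in AVFP 3, and at 6351.1 TPM and 5887 FPKM in AVFP 2, where the ratio equals that of the library. Estimated counts, on which every test ran, were compared with FPKM for Bcl3, Hp, Lbp and Lcn2. Departures over 0.2 in log2 were 1.17 for Bcl3, -0.34 for Lbp and -0.91 for Lcn2 in AVFP 1. In AVFP 3 they were -0.39 for Bcl3 and 1.36 for Lcn2, and in AVFP 2 they were -0.50 for Lbp and -0.21 for Lcn2. Gstp2 and Cebpd were too low in some libraries for this comparison, so their counts were not checked in this way. Cebpd had 147 counts at 2.85 FPKM in AVFP 1 and 165 counts at 8.44 FPKM in AVFP 3.

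Values of these 6 genes in AVFP 1 and AVFP 3 depart from the library's ratio by up to 1.82-fold, which is too much for rounding to 2 decimals. TPM sums fall short of 1000000 by 19170 in AVFP 1 and 40395 in AVFP 3. Genes outside the table are argued against as the place of that TPM only by the other 7 libraries, where table genes sum to 999999 or 1000000 TPM. All 6 genes depart from the ratio in each library with a shortfall, and 0 do in the other 7. The 6 genes were picked by these departures, which therefore cannot locate the missing TPM. All other genes compared keep the ratio within 2%. The 6 genes summed to 4347.8 TPM in AVFP 1 and 8679.9 TPM in AVFP 3. They summed to 7418.4 TPM in AVFP 2, 7928.9 to 10260 TPM in control and 16599 to 27400 TPM in the model. Whether the missing TPM belongs to the 6 genes and how their values came to disagree stay open. No biological explanation was tested, and the AVFP values of Hp, Lcn2 and the other 4 genes are uncertain.

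Libraries labelled spleen are led by hepatocyte transcripts. Spleen as the main tissue with some liver RNA carried over is argued against by B cell and T cell genes, which reach at most 0.0125% of the hepatocyte list. Kupffer cell Clec4f exceeds red pulp Spic in 9 of 9 libraries, which is consistent with liver as the tissue sampled. Whether samples were exchanged or labelled otherwise stays open. The lists for immune cells could then measure leukocytes within that tissue, but not through every member. Lcn2, which hepatocytes also make, held 8653.2 of the 9443.5 TPM of the neutrophil list in model 1.

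Genes of blood and leukocytes are lower in model and AVFP than in control libraries. More blood of 1 composition in the controls stays open: the ratio of S100a8 to Hba-a1 differs 76.6-fold among the 3 control libraries, but 9.70-fold without control 1, and rests on 2 genes. Control 1 alone is argued against by the neutrophil list, whose limma voom median in model against control without control 1 is -3.16. Loss of leukocytes and erythroid cells after cyclophosphamide was not tested here and stays open, as does blood left in the tissue in differing amounts.

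Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. In model against control the real grouping called 13 genes and the highest other split 1, so 1 of 10 splits called as many. In AVFP against model the real grouping called 0 and the highest other split 1. With 0 called, 10 of 10 splits call as many by definition, so that count cannot decide. By unadjusted p under 0.05 the real grouping had 450 genes and the highest other split 1369, and 4 of 10 splits had as many. In AVFP against control the real grouping called 9 and the highest other split 0, so 1 of 10 called as many.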

How the results depend on the processing

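Tests without 6 discordant genes, without control 1 and AVFP 3, or by limma voom with equal weights were chosen only after results were seen. Against 0 genes with edgeR in each comparison, RLE scaling and a minimum log2 fold change of 1 also gave 0. For model against control DESeq2 called 71, voom with quality weights 126, the 6 libraries alone 13, and leaving out control 1 and AVFP 3 called 2. For AVFP against model DESeq2 called 6. For AVFP against control DESeq2 called 301, quality weights 8, equal weights 3, upper-quartile scaling 2, no filter 15, the stricter filter 4, the 6 libraries alone 9, an adjusted p under 0.1 gave 19, leaving out the 6 genes 2, and leaving out control 1 and AVFP 3 gave 3. DESeq2 called 2 genes in opposite directions and 24 of the 30 gene results picked by the naming rule. Leaving out 1 library gave 0 to 3 genes, 0 to 1 and 0 to 70 in the 3 comparisons, and 0 to 10 named gene results. Camera called 21 of 90 fixed list tests, 0 with an estimated correlation, 3 by fry, and 18 to 29 without 1 library.

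With replicate number as a block, 3 genes, 0 and 13 were called, with 8 named gene results; 6 of 9 libraries, not all, correlate best with their own number, with r from -0.097 to 0.235 between same-numbered libraries. That is a hint from the data, not the design, and whether numbers pair samples stays open.

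In limma voom medians without 1 library, AVFP against model, the acute phase list lay between -0.77 and 0.48 (reversed without AVFP 2), and the major urinary protein list between -1.73 and 0.73 (reversed without model 2); the cause was not tested. In simulated data at this depth 28.0% of 2-fold changes were called. That share holds for the simulated counts, which lack the libraries that stand apart here.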

Other observations

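Cxcl1, Marco and Junb were chosen after their values were seen, and the fixed lists for cytokines and Toll-like receptor signalling did not pass in any comparison. Cxcl1 (gene ID 14825), a neutrophil chemokine, averaged 147 ± 74.8 CPM in the model, 166 ± 106 CPM with AVFP and 22.1 ± 2.21 CPM in control (SD, n = 3 per group). Marco (gene ID 17167), a scavenger receptor of macrophages, averaged 16.5 ± 5.80, 31.6 ± 28.2 and 3.44 ± 1.34 CPM in the same order, and rose in AVFP against control when adjusted over the Kupffer cell list alone (log2 3.20). Junb, an AP-1 transcription factor, rose over its list alone in model against control (1.48) and AVFP against control (1.75).

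Sds (gene ID 231691), serine dehydratase, averaged 349 ± 41.3 CPM in the model, 384 ± 53.2 CPM with AVFP and 189 ± 27.9 CPM in control (SD, n = 3 per group). Over the gluconeogenesis list alone Sds rose and G6pc fell in model against control (0.89 and -1.59) and in AVFP against control (1.02 and -2.03). Acly (-1.11), the citrate lyase that feeds lipid synthesis, and Elovl5 (-1.17), a fatty acid elongase, fell over the fatty acid synthesis list alone in AVFP against control, as did Elovl6 (-0.97), while Angptl8 (2.26) rose.

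Genes of the Y chromosome were lower in AVFP 3 than in the other 8 libraries. Eif2s3y was at 1.09 TPM there and at 11.8 to 25.1 TPM elsewhere, Kdm5d at 0.29 against 0.96 to 3.05 TPM, Uty at 0.92 against 1.95 to 4.61 TPM, and Ddx3y at 3.42 against 4.36 to 7.10 TPM. Alb was at 14727 TPM in AVFP 3 and at 35748 TPM or more elsewhere. Each of these Y chromosome genes was still detected in AVFP 3, which alone does not tell the sex of that sample. The labels used here give no sex, and whether AVFP 3 differs in sex or in another way was not tested. Major urinary proteins and cytochromes P450 include genes that differ between the sexes in mouse liver. Without AVFP 3 the limma voom median of major urinary proteins in AVFP against control was still -1.61, though the call ended (camera adjusted p = 0.0807), so the lower values do not rest on AVFP 3 alone. That of cytochrome P450 in AVFP against model was 0.10 (0.820).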
